A study of Solanum lycopersicum with 24 samples.

How the data were processed

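Leaves of tomato (Solanum lycopersicum) plants at the flowering stage were profiled on 24 Affymetrix arrays, 12 in a drought experiment and 12 in a heat experiment. Each experiment compared a susceptible and a tolerant genotype, each as control and as stressed plants, which made 8 groups of 3 arrays. Per the labels' protocols, stressed plants of the drought experiment went without water for 7 days and those of the heat experiment were held at 40 C for 60 min before sampling. Total RNA was taken with Trizol and labelled with biotin, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. These name susceptible and tolerant plants within each experiment and do not say that both experiments used the same genotypes. The labels do not say that the 3 replicates of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

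The deposited expression values were log2 values per probe set, made with Affymetrix Expression Console and RMA 1.0 per the submitters' processing notes. Whether all 24 arrays were normalized in a single run is not given in the sources used here. The authors also deposited a table per experiment with the fold change between stressed and control means as a linear ratio of at least 1, with its direction beside it. Per the file headers, these tables list probe sets with a genotype by treatment term under a corrected p of 0.05 and a fold change of 2 or more in at least 1 genotype. The group means in those tables were on a log2 scale relative to a baseline per probe set, as their values show, and were not used.

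The value table held 10209 probe sets. The 108 AFFX control probe sets were left out of all tests and used as measures of spike-in signal and RNA integrity, which left 10101 probe sets. These still held 63 probe sets for reporter genes that are not tomato sequences, and they were used as a measure of background. Each experiment was fitted with limma 3.58.1 in R 4.3.3 as a model of 4 group means (lmFit and eBayes) on the deposited log2 values with no further normalization. From it came the response to stress in each genotype, the difference between both responses, and the difference between genotypes in control and in stressed plants. P-values were adjusted by Benjamini and Hochberg over the 10101 probe sets, and a probe set was called at an adjusted p under 0.05. After seeing the data, a rule was added for signal near background in the genes discussed. Where a gene lay at or under the 95th percentile of the reporter probe sets on at least 2 of 3 arrays of its dimmer group, its difference is given as a bound. For the bound each array under that percentile was raised to that percentile, while calls and p-values stayed those of the limma fit. The bound of a difference of responses is that of both responses combined, and it exists only where a larger response would widen the difference. Where the brighter group lay within that range, no difference is given from that fit. No probe set was called on the absence of signal, and no levels were compared between probe sets.

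Gene names came from the authors' deposited tables, the only files used here that pair probe sets with genes, so a named gene had been selected on these samples for a difference in response. A single symbol was found for 460 probe sets and several symbols for 15, and 9734 had none here. Of 153 locus symbols looked up in the RefSeq gene table, 67 received another symbol. No genome was used, so no positions are given. Probe sets whose identifiers carry the suffix _s_at or _a_at can match related transcripts, and among the genes discussed this concerns CALM1LE, Lehsp90-2, BI-GST/GPX, systemin, ERF3 and LOC778315. A set of 26 gene lists was defined by patterns on symbols and titles, and 24 of them found a named member. The 16 lists with at least 5 genes were tested in each of the 10 comparisons with camera in limma. The test used 1 probe set per gene, a preset correlation between genes of 0.01, the named genes as background and Benjamini-Hochberg adjustment over the lists of a comparison. Members of 4 lists whose titles show another product were left out in an alternative run.

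Genes discussed for a stress response or a difference of responses were the 10 largest increases and 10 largest decreases among called probe sets with an informative name. For single responses the replicates of both groups also had to be free of overlap. The same rule took 5 and 5 genes for each comparison of genotypes, with 1 probe set per gene. From every list, up to 2 of the largest increases and 2 of the largest decreases were added, or the 2 smallest p-values where no member was called. A few further members are given for lists discussed in detail and were chosen after their values were seen.

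Alternatives covered repeated quantile normalization, centring of arrays on their medians, removal of the dimmest 25 percent of probe sets, a trend in the variance, array weights, all 24 arrays in a single model, only the 6 arrays compared, the replicate number as a block, a minimum log2 difference of 1 and removal of each array in turn. The groups, tests, lists, the rule for the genes discussed and these alternatives were fixed before the data were examined. After seeing the data, 6 alternatives were added. These left out the reporter probe sets, added an RNA integrity covariate from the actin, gapdh and ef1a probe sets or from gapdh alone, left out replicate 3 of both tolerant heat groups, restricted the lists by title, and added unnamed probe sets to the background of the list test. Array weights were estimated gene by gene in both experiments, since the default method did not converge in the heat experiment and gave tolerant control 1 a weight of 459.5.

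The scripts were tested on simulated arrays in which each probe set had a single spread, pooled over the 4 groups, with independent noise. Of 10101 probe sets, 67, 67 and 66 were changed by 0.5, 1 and 2. The real spread was unequal, with median SDs between replicates of 0.0854 and 0.0743 in susceptible control and stressed drought groups. In the tolerant drought groups they were 0.305 and 0.393, so the shares and false calls below do not describe arrays of unequal spread. In the simulated drought response of the tolerant genotype, 20.9% of changes of 0.5, 35.8% of changes of 1 and 77.3% of changes of 2 on the log2 scale were called. For the difference of drought responses these shares were 0%, 20.9% and 54.5%. In the simulated heat response of the tolerant genotype they were 28.4%, 64.2% and 93.9%, and for the difference of heat responses 2.99%, 38.8% and 78.8%. At most 7 unchanged probe sets were called in any simulated comparison.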

Results

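The series measured transcript levels in leaves of tomato plants at the flowering stage, in order to compare how susceptible and tolerant plants respond to drought and to heat. Each of the 8 groups had 3 arrays. Levels are given as log2 values with the SD over 3 arrays, and differences on the log2 scale with their standard error from the limma fit. Each fit used a single spread per probe set over its 4 groups, although replicates of tolerant groups varied more. Standard errors and p-values of responses in tolerant plants may therefore be too small. Where at least 2 arrays of the dimmer group lay within the range of the reporter probe sets, a measure of background, a difference is given as a bound, as at least a value or as a value or lower. Array medians averaged between 7.21 and 7.58 in the 8 groups. Replicate arrays correlated at 0.9974 or higher in the susceptible drought groups and between 0.919 and 0.963 in the tolerant drought groups. In the heat experiment the correlation was at least 0.9967 in susceptible groups and between 0.9461 and 0.9978 in tolerant groups.

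Control probe sets differed between groups. The bioB spike-in, a bacterial transcript added to each sample, stood at 5.91 ± 0.12 in susceptible control and 6.17 ± 0.82 in susceptible stressed arrays of the drought experiment. It stood at 10.86 ± 0.20 and 11.46 ± 0.17 on the corresponding tolerant arrays. In the heat experiment the same signal lay between 6.35 and 7.06 in all 4 groups. The signal of the 3' minus the 5' probe set of gapdh, a measure of RNA integrity, was 1.60 ± 0.09 and 0.80 ± 0.08 in susceptible control and stressed heat arrays. It was 4.78 ± 1.02 in tolerant control and 2.65 ± 0.67 in tolerant stressed heat arrays. For ef1a it went the other way, with 4.09 ± 0.84 in tolerant control and 5.74 ± 0.82 in tolerant stressed heat arrays, and for actin it was 4.48 ± 0.66 and 4.01 ± 0.78. In the drought experiment the mean of these 3 transcripts was 1.25 ± 0.12 and 0.75 ± 0.05 on susceptible control and stressed arrays and 2.89 ± 0.91 and 1.64 ± 0.08 on tolerant ones, so it moved with the genotype and with the treatment in both. The median of the reporter probe sets, which match no tomato sequence, was 4.43 ± 0.53 in tolerant control heat arrays and between 3.42 and 3.54 in the other 3 heat groups. In the drought experiment it was 3.08 and 3.10 on susceptible arrays and 4.06 and 4.38 on tolerant arrays.

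**Figure D1:**
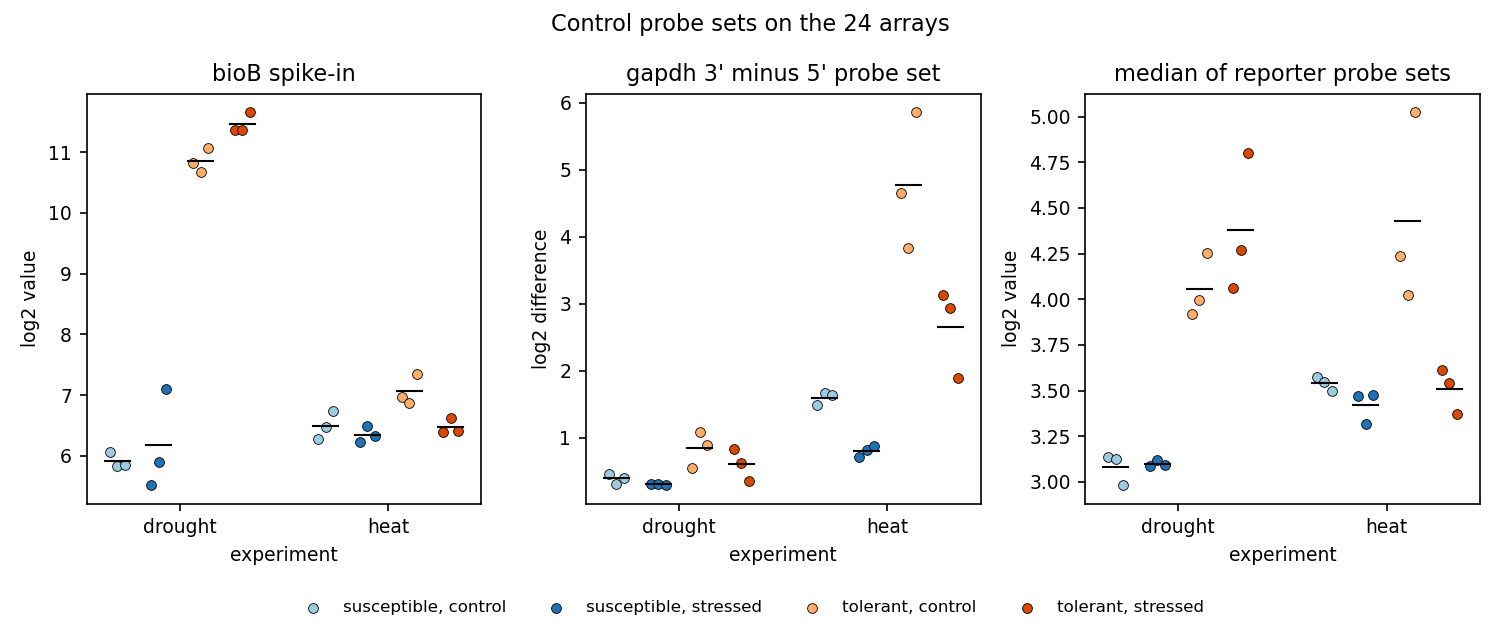
Control signals on each of the 24 arrays by experiment, as log2 values of the bioB spike-in (left), the log2 difference between the 3' and 5' gapdh probe sets (middle) and the median log2 value of 63 reporter probe sets (right). Points are arrays, coloured by genotype and treatment, and bars are means of 3 arrays; bioB averaged 10.86 and 11.46 on tolerant drought arrays against 5.91 and 6.17 on susceptible ones.

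Calls at an adjusted p under 0.05 were numerous in all 10 comparisons. Counts within lists are of named genes, which the authors' tables had selected on these samples for a difference in response. Such counts are thus not independent evidence of a direction or of a difference between responses. Some counted genes lay within the reporter range in their brighter group too, and their number is given for comparisons of 2 groups.

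**Figure D2:**
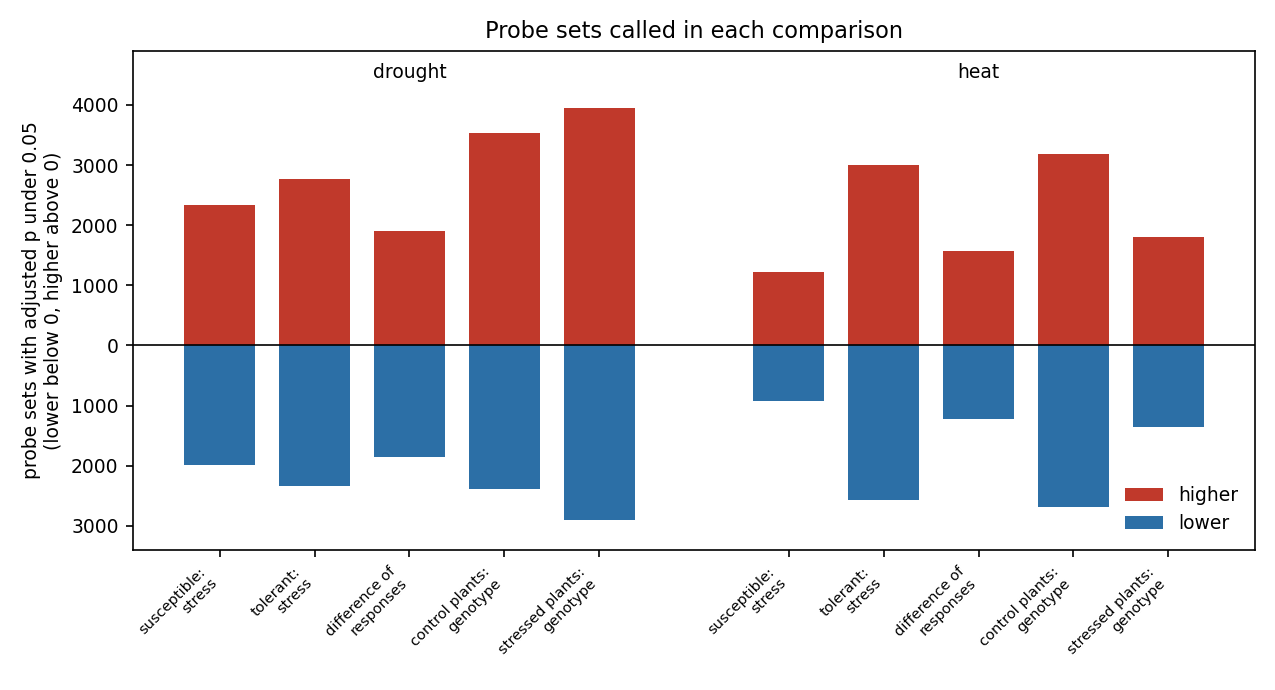
Number of probe sets called higher (above 0) and lower (below 0) in each of the 10 comparisons, of 10101 tested, at a limma adjusted p under 0.05. The counts ran from 2150 for the heat response of the susceptible genotype to 6852 for the genotypes under drought.

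The response of the susceptible genotype to 7 days without water was compared with its own control plants. Most named genes for cell wall remodelling and all 9 for cell division fell, and 12 of 16 for pathogenesis-related (PR) proteins, which plants make in response to pathogens, rose. The xyloglucan transferase ext fell from 11.89 ± 0.10 to 4.17 ± 0.18, within the reporter range, a change of -7.49 or lower (adjusted p = 1.66e-10). The chitinase CHI3 rose by 5.91 ± 0.12, from 7.51 ± 0.16 to 13.43 ± 0.08 (adjusted p = 3.63e-10). PR1b1, a PR-1 protein, rose by at least 5.77, from 4.77 ± 1.41 to 10.77 ± 0.004 (adjusted p = 4.98e-05).

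Of 28 named genes for cell wall loosening and synthesis, 21 were lower and 2 higher, with the same counts when adjusted over the list alone. The list was shifted down against the other named genes (camera adjusted p = 0.000248, and adjusted p = 0.0193 with an estimated correlation). Besides ext, the transferase XTH7 changed by -5.71 or lower and the expansin LeEXP2, which loosens walls of growing cells, by -5.25 or lower. The 2 higher members were the extensin LOC544158 (1.33) and XTH5 (1.51). All 9 named histone and cell cycle genes were lower, also over the list alone, among them H2B-2 (-5.48 ± 0.22), the cyclin CycA2 (-5.04 or lower) and the histone H4 gene LOC544081 (-4.77). Their adjusted p was 0.0021, and adjusted p = 0.0511 with an estimated correlation. Repeated quantile normalization left 8 of these 9 called.

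Of 16 PR proteins, 12 were higher and 1 lower, with the same counts over the list alone (adjusted p = 0.00152, and adjusted p = 0.0304 with an estimated correlation), and 1 of the 12 lay within the reporter range. P4 rose by at least 4.66 and the osmotin-like NP24-I by 4.06, and the lower member was the PR5-like LOC543878 (-2.80). Among other large increases were the carbonic anhydrase ca3 (6.50 ± 0.56), the protease pip1 (6.23 ± 0.48), the ribonuclease rnale (5.50 ± 0.46), the chloroplast small heat shock protein HSP21 (4.96 ± 0.27), calmodulin CALM1LE (4.67 ± 0.43) and the dehydrin TAS14 (4.03), a hydrophilic protein of drying tissue. Decreases included the auxin-response gene IAA10 (-5.72 or lower), the gamma-thionin-like TPP3 (-4.74 or lower), the inositol phosphate synthase Inps (-5.17), the wound-signal precursor systemin (-3.27) and NCED1 (-3.01), an enzyme of abscisic acid synthesis. Of 9 light-harvesting and electron transport genes, 7 were lower (8 over the list alone) and 1 was higher (adjusted p = 0.196). The chlorophyll-binding CAB5 changed by -3.46, and the photosystem II gene PSBR by 4.23 ± 0.13.

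In all, 4324 of 10101 probe sets were called, 2331 higher and 1993 lower. Among all 10101 probe sets, called or not, the replicates of both groups did not overlap for 77.01%, where 10% would do so without a difference. The count depended on which arrays set the spread, with 7502 calls from the 6 susceptible arrays alone, 7435 with array weights and 2445 at a log2 difference of at least 1.

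In the tolerant genotype, drought raised TAS14 and SNF4 and lowered 24 of 28 cell wall and 8 of 9 cell cycle genes. TAS14 rose by at least 5.61, from 4.69 ± 0.35 to 11.41 ± 0.13 (adjusted p = 5.03e-09). SNF4, a subunit of an energy-sensing protein kinase, rose by at least 3.58, from 4.34 ± 0.54 to 9.38 ± 0.11 (adjusted p = 2.09e-07). PR1b1 fell from 10.85 ± 0.10 to 3.68 ± 1.14, within the reporter range, a change of -4.66 or lower (adjusted p = 1.33e-05), and P4 changed by -2.68 or lower.

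Of the 28 cell wall genes, 24 were lower and 2 higher (3 higher over the list alone; adjusted p = 0.00563, and adjusted p = 0.0604 with an estimated correlation). The decreases included ext (-4.32 ± 0.13), the endoglucanase cellulase (-4.06) and the expansin exp9 (-3.07 or lower), and 2 of the 24 lay within the reporter range. The increases were XET4 (at least 0.90) and the extensin LOC544058, whose signal lay within the reporter range in both groups. Of the 9 histone and cell cycle genes 8 were lower, also over the list alone, led by LOC544081 (-4.42 ± 0.18) and the kinase cdkB2 (-3.18 or lower). The list had an adjusted p of 0.0267, and adjusted p = 0.184 with an estimated correlation. Light harvesting had 7 lower and 1 higher of 9 genes (adjusted p = 0.0571), with CAB5 at -3.96 and CAB6A at -2.84, and the chlorophyll synthesis enzyme POR2 changed by -3.78 or lower. The aquaporin-like LOC778315 changed by -4.53 ± 0.16, and LeTIP, another water channel by its name, by -2.79 or lower.

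Increases included the proteinase inhibitor ER1 (at least 3.83), the sucrose synthase sus3 (3.05 ± 0.09), the jasmonate-linked LEJA2 (at least 1.63), the protein phosphatase 2C DIG3 (2.82 ± 0.39) and LeAREB (2.55), a relative of abscisic acid response factors. The late-embryogenesis-like ER5 rose by 2.00. The list that held TAS14, ER5 and ASR1 had 8 of 11 genes higher and 1 lower (adjusted p = 0.0541), but its other members are not dehydrins or related proteins by title. ASR1 changed by -0.08 (adjusted p = 0.678). All 5 clock and light signalling genes were higher, also over the list alone (adjusted p = 0.0541), with CIP2b at 2.22 and CO1 at 1.08. CO1 was no longer called under most alternatives, and its value was 0.61 without tolerant control replicate 3.

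The fit called 5110 probe sets, 2769 higher and 2341 lower. Of all probe sets tested, called or not, 48.19% had replicates that did not overlap. The median SD between replicates was 0.305 and 0.393 in tolerant control and stressed groups, against 0.0854 and 0.0743 in the susceptible groups of the same fit. The 6 tolerant arrays alone gave 3109 calls, and 2878 calls of the main fit had a log2 difference of at least 1. An RNA integrity covariate, chosen after seeing the data, gave 3637.

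The difference between both drought responses was tested directly, as tolerant minus susceptible. PR1b1 differed by -10.43 or lower (adjusted p = 6.51e-06) and P4 by -7.34 or lower (adjusted p = 7.77e-08), each rising in susceptible and falling in tolerant plants. Of the 16 PR genes, 11 had a lower and 1 a higher response in tolerant plants (12 and 1 over the list alone; adjusted p = 0.00556, and adjusted p = 0.0771 with an estimated correlation). The subtilisin-like protease P69B differed by -4.27 or lower and CHI3 by -4.74 ± 0.17, and the higher response was that of PR-P2 (1.53).

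Genes with a higher response in tolerant plants included IAA10 (at least 6.22), TPP3 (at least 5.38), the endoglucanase Cel1 (at least 5.41), SNF4 (at least 3.66), Inps (5.04 ± 0.12), the carotene hydroxylase CrtR-b2 (4.42 ± 0.48) and systemin (4.18 ± 0.13). NCED1 differed by 3.13, having changed by -3.01 in susceptible and by 0.12 (adjusted p = 0.517) in tolerant plants. Lower responses were found for pip1 (-8.27 ± 0.68), ca3 (-6.59 ± 0.80) and HSP21 (-4.55), which changed by 0.41 (adjusted p = 0.243) in tolerant plants. TAS14 rose in both genotypes and its responses differed by at least 1.58. Histone and cell cycle genes differed in only 2 of 9 cases, H2B-2 (2.85) and CycA2, the latter within the reporter range in stressed plants. After repeated quantile normalization 1 gene of that list was higher and 1 lower.

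**Figure D3:**
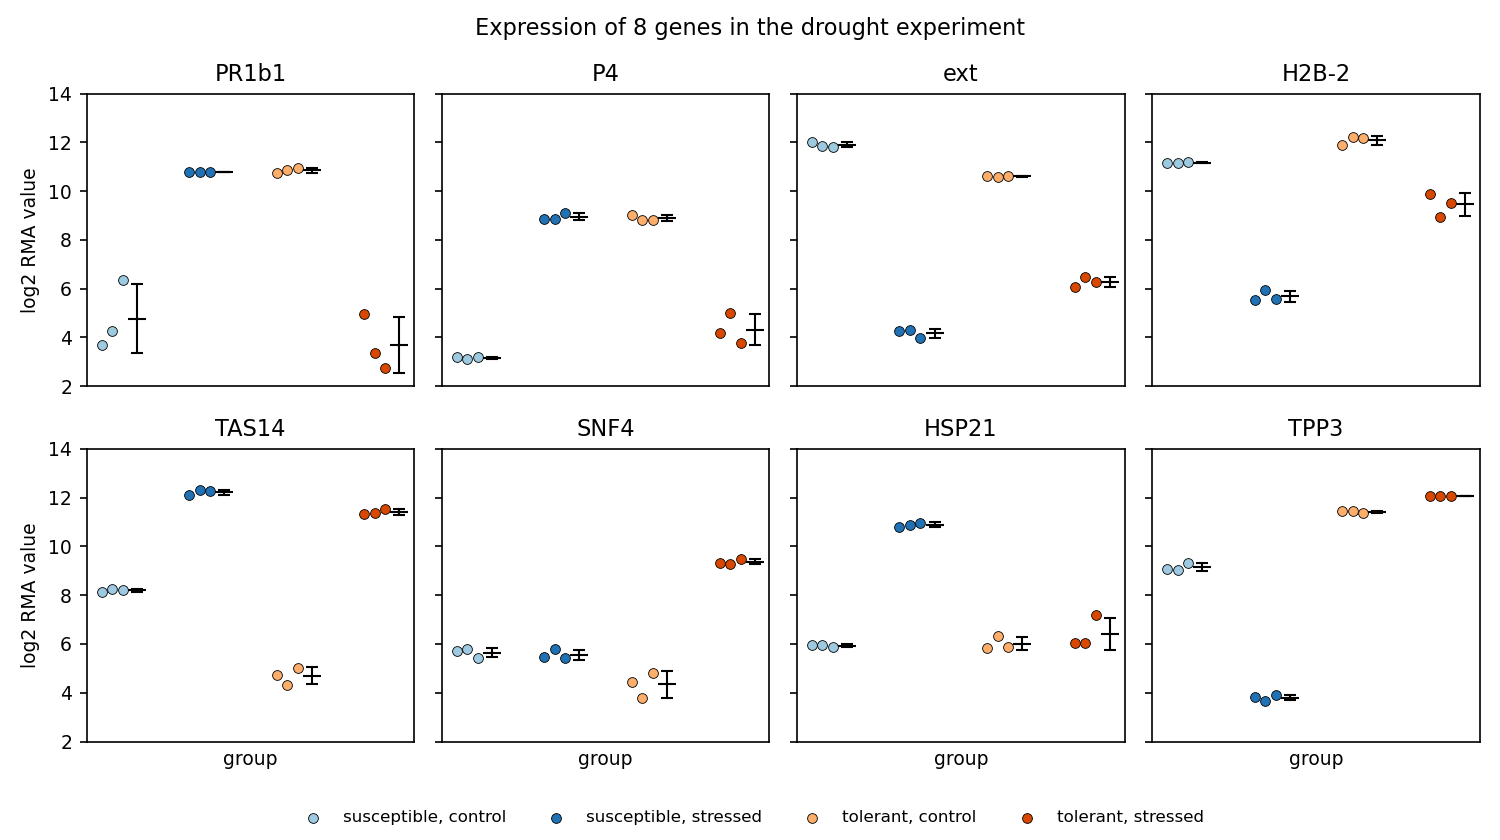
Log2 expression of 8 genes in the drought experiment, with 3 arrays per group as points and the mean with its SD as bars. PR1b1 averaged 4.77 and 10.77 in susceptible control and stressed plants and 10.85 and 3.68 in tolerant ones, ext fell in both genotypes and SNF4 rose by at least 3.58 in tolerant plants.

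The difference was called for 3753 probe sets, 1902 with a higher and 1851 with a lower response in tolerant plants. Both genotypes shared 1155 increases, where 639 would be shared by independent lists, and 1103 decreases against 461.9. A further 266 probe sets rose in susceptible and fell in tolerant plants, against 540.2 for independent lists, and 294 went the other way against 546.3.

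Genotypes were also compared within control and within stressed plants of the drought experiment. In control plants, PR-5 was higher in tolerant leaves by at least 5.37 (adjusted p = 1.62e-08), PR1b1 by at least 5.85 and P4 by at least 4.59, and 10 of the 16 PR genes were higher and 3 lower, also over the list alone (adjusted p = 0.0701). The mitochondrial small heat shock protein LEMTSHP was lower (-3.35 or lower), as were the jasmonate synthesis gene aos (-4.23 ± 0.48), ER5 (-4.09 ± 0.31) and the coactivator ER24 (-3.79 ± 0.53). The ethylene list had 13 lower and 6 higher genes of 23 (adjusted p = 0.216).

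In stressed plants 10 PR genes were lower and 2 higher in tolerant leaves, also over the list alone (adjusted p = 0.0591), with PR1b1 at -4.58 or lower. TPP3 was higher by at least 7.66 (adjusted p = 4.72e-11) and systemin by 5.38 ± 0.09, while the jasmonate synthesis enzyme opr was at -4.51 or lower and the tyramine transferase THT7-1 at -4.22 or lower. Light harvesting had 8 lower and 1 higher of 9 genes (adjusted p = 0.045, and adjusted p = 0.198 with an estimated correlation). CAB6A was at -3.17, and the higher member was psbF (5.08 ± 0.18). Histone and cell cycle genes had 7 higher of 9 (adjusted p = 0.045, and adjusted p = 0.14 with an estimated correlation), of which repeated quantile normalization left 2 and 3 lay within the reporter range. The 7 marker genes of flowers and pollen were all higher (adjusted p = 0.0306, and adjusted p = 0.14 with an estimated correlation), among them the APETALA3 homolog LOC543555 (at least 3.06) and TDR3 (2.65), but 2 of the 7 lay within the reporter range and repeated quantile normalization left 6. All 5 clock and light signalling genes were higher too (adjusted p = 0.045, and adjusted p = 0.14 with an estimated correlation), led by CO1 (2.64). For each of these 4 lists the counts over the list alone were the same. With all probe sets of a gene in the test, adjusted p was 0.066 for light harvesting and 0.054 for both the cell cycle and the clock genes. Reporter probe sets moved in the same direction as the last 3 lists, with a median difference of 1.17 in stressed and 0.94 in control plants.

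The genotypes differed at 5912 probe sets in control plants, 3525 higher and 2387 lower in tolerant leaves, and at 6852 in stressed plants, 3953 higher and 2899 lower. These splits depended on normalization and dim probe sets, with 2715 higher and 2379 lower in control and 3095 and 2774 in stressed plants after repeated quantile normalization, and 2348 and 2320 in control and 2542 and 2736 in stressed plants without the dimmest 25 percent. Of all probe sets tested, called or not, 72.86% in control and 75.05% in stressed plants had replicates that did not overlap. Of the 63 reporter probe sets, 31 and 44 were called as well, and an RNA integrity covariate chosen after seeing the data left 3317 calls in control plants.

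The heat response of the susceptible genotype was compared with its own control plants. All 5 named small heat shock proteins, which bind unfolded proteins, rose. Of the named cell wall and cell cycle genes, 13 of 28 and 7 of 9 fell. The small heat shock protein vis1 rose by 4.17 ± 0.10, from 7.585 ± 0.05 to 11.76 ± 0.04 (adjusted p = 3.21e-10). The ACC synthase ACS7B, of ethylene synthesis, fell from 8.13 ± 0.14 to 4.16 ± 0.12, within the reporter range, a change of -3.41 or lower (adjusted p = 1.51e-08).

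All 5 small heat shock proteins were higher, also over the list alone (adjusted p = 0.000172, and adjusted p = 0.0302 with an estimated correlation), with leer-sHSP at 3.74 ± 0.13, HSP21 at 3.25 ± 0.14 and LEMTSHP at 2.92 ± 0.14. Of 9 large chaperones 5 were higher and none lower (6 over the list alone; adjusted p = 0.0211, and adjusted p = 0.394 with an estimated correlation). These included the cognate chaperone ER21 (2.45 ± 0.14), HSP90 (at least 1.43) and BiP/grp78 (2.06), a chaperone of the endoplasmic reticulum. Other increases were ER24 (3.40 ± 0.12), the elongation factor LOC544055 (3.09 ± 0.14), the auxin-binding protein ERabp1 (2.85 ± 0.11), the GTPase SAR2 (2.78 ± 0.17), the carboxylase kinase PPCK2 (2.28 ± 0.16) and the dehydration-response factor DREB1 (2.20).

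Of the 28 cell wall genes, 13 were lower and 2 higher (14 and 2 over the list alone; adjusted p = 0.00459, and adjusted p = 0.377 with an estimated correlation), with tXET-B1 at -2.34 ± 0.13 and Cel1 at -1.80. The higher members were LeEXP2 (0.83) and exp11 (0.64). Of the 9 histone and cell cycle genes, 7 were lower, also over the list alone (adjusted p = 0.02, and adjusted p = 0.539 with an estimated correlation), with H2B-2 at -1.03 and cdkB2 at -0.68, and 1 of the 7 lay within the reporter range. PR proteins had 7 lower and 1 higher of 16 genes, also over the list alone (adjusted p = 0.0702), with GluB at -2.55 or lower, pr p23 at -2.31 and NP24-I at -2.08. Further decreases included an auxin-regulated kinase, LOC543684 (-3.04 or lower), the transferase THT1-3 (-2.86 ± 0.19) and the transcription factor WRKYIId-2 (-2.66 ± 0.17).

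The fit called 2150 probe sets, 1226 higher and 924 lower. Of all probe sets tested, called or not, 54.63% had replicates that did not overlap. Array weights gave 5472 calls and the 6 susceptible arrays alone 4431, and centring of arrays turned the split to 986 higher and 1314 lower.

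In the tolerant genotype the same small heat shock proteins rose with heat, and all named cell cycle genes fell. The list of 5 small heat shock proteins was higher throughout, also over the list alone (adjusted p = 0.0045, and adjusted p = 0.121 with an estimated correlation), with leer-sHSP at 3.82 ± 0.13 and vis1 at 3.39 ± 0.10. All 9 histone and cell cycle genes were lower, also over the list alone (adjusted p = 1.32e-05, and adjusted p = 0.323 with an estimated correlation). The kinase cdkB2 changed by -2.65 ± 0.14, the replication factor pcna by -2.42 ± 0.14 and the cyclin CycB2 by -1.34 or lower. The kinesin TKR, a microtubule motor, changed by -4.41 ± 0.14 (adjusted p = 9.07e-09).

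Large chaperones were higher in 8 of 9 cases and lower in none, also over the list alone (adjusted p = 0.261), with Lehsp90-2 at 0.32 or higher. The 8 became 6 after repeated quantile normalization and 4 after centring of arrays. Increases outside these lists were the asparagine synthetase AS1 (3.60 ± 0.15), the threonine deaminase Td (2.88 ± 0.13), the auxin response factor ARF2 (2.79 ± 0.44), the wound-inducible carboxypeptidase LOC544223 (2.63 ± 0.14) and the metallothionein MTA (2.44 ± 0.42). Decreases were the extensin-like LOC543740 (-3.06 ± 0.24), ACS7B (-2.82 ± 0.15) and the gamma-thionin TGAS118 (-2.33 ± 0.16). Cell wall genes were higher in 7 and lower in 8 of 28 cases, also over the list alone, and centring of arrays made this 4 and 14. Of the 8 lower, 2 lay within the reporter range.

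The fit called 5564 probe sets, 2992 higher and 2572 lower. Replicates were free of overlap for 55.91% of all probe sets tested, called or not. Reporter probe sets fell along with the cell cycle genes, by a median of 0.86, with 45 of 63 called, and the gapdh 3' minus 5' signal was 4.78 in control and 2.65 in stressed arrays. Centring of arrays, which set the median of all probe sets at -0.27 rather than 0.01, gave 1928 higher and 4334 lower, repeated quantile normalization gave 2501 and 2943, and leaving out the dimmest 25 percent gave 2845 and 1447. A covariate for the gapdh signal, chosen after seeing the data, left 2445 calls and ended those of ARF2 (0.69), MTA (0.39) and Lehsp90-2 (0.39). Of 98 shuffles of that signal within groups, 43 kept as low a share of calls, so these losses decide little about RNA integrity. The 6 tolerant arrays alone gave 3174 calls.

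The difference between both heat responses was tested as tolerant minus susceptible. Single genes for defence, ethylene and gene regulation differed. The transcription regulator GRAS1 differed by at least 2.79, ASR1, a small protein of ripening and water stress, by 3.74 ± 0.59 and the carboxypeptidase inhibitor mcpi by 3.73 ± 0.22 (adjusted p = 5.09e-06). ASR1 fell in susceptible plants, from between 10.72 and 11.105 in control to between 8.182 and 8.528 in stressed arrays. Its tolerant control (7.132 to 8.37) and stressed arrays (8.357 to 10.037) overlapped. GluB differed by at least 3.18, the ethylene factor ERF3 by 3.08 ± 0.39, the ACC synthase LE-ACS3 by at least 1.59 and NP24-I by 2.67 ± 0.37.

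DREB1 differed by -3.43 ± 0.32 (adjusted p = 4.68e-05), since it rose by 2.20 in susceptible and changed by -1.24 in tolerant plants. PPCK2 (-3.17 ± 0.23) and PPCK1 (-3.15 ± 0.24) behaved alike, rising by 2.28 and 2.27 in susceptible plants and changing by -0.89 and -0.88 in tolerant ones. With the gapdh covariate, chosen after seeing the data, the changes in tolerant plants were -0.33 for DREB1, -0.39 for PPCK2 and -0.77 for PPCK1. These were no longer called, while the differences of responses stayed called. The gapdh signal differed between tolerant control and stressed arrays, so the lost calls do not tell RNA integrity apart from heat. TKR differed by -3.21 ± 0.20 and ER24 by -2.69 ± 0.18. Of the 9 histone and cell cycle genes, 6 had a lower response in tolerant plants, also over the list alone (adjusted p = 0.0204, and adjusted p = 0.775 with an estimated correlation), with pcna at -2.19 and cdkB2 at -1.97. Reporter probe sets moved in the same direction, with a median of -0.77 and 24 of 63 called, beside a median of -1.05 for the list. Small heat shock proteins had 2 lower responses of 5 and none higher, also over the list alone (adjusted p = 0.347), namely LEMTSHP (-1.01) and vis1 (-0.78).

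**Figure D4:**
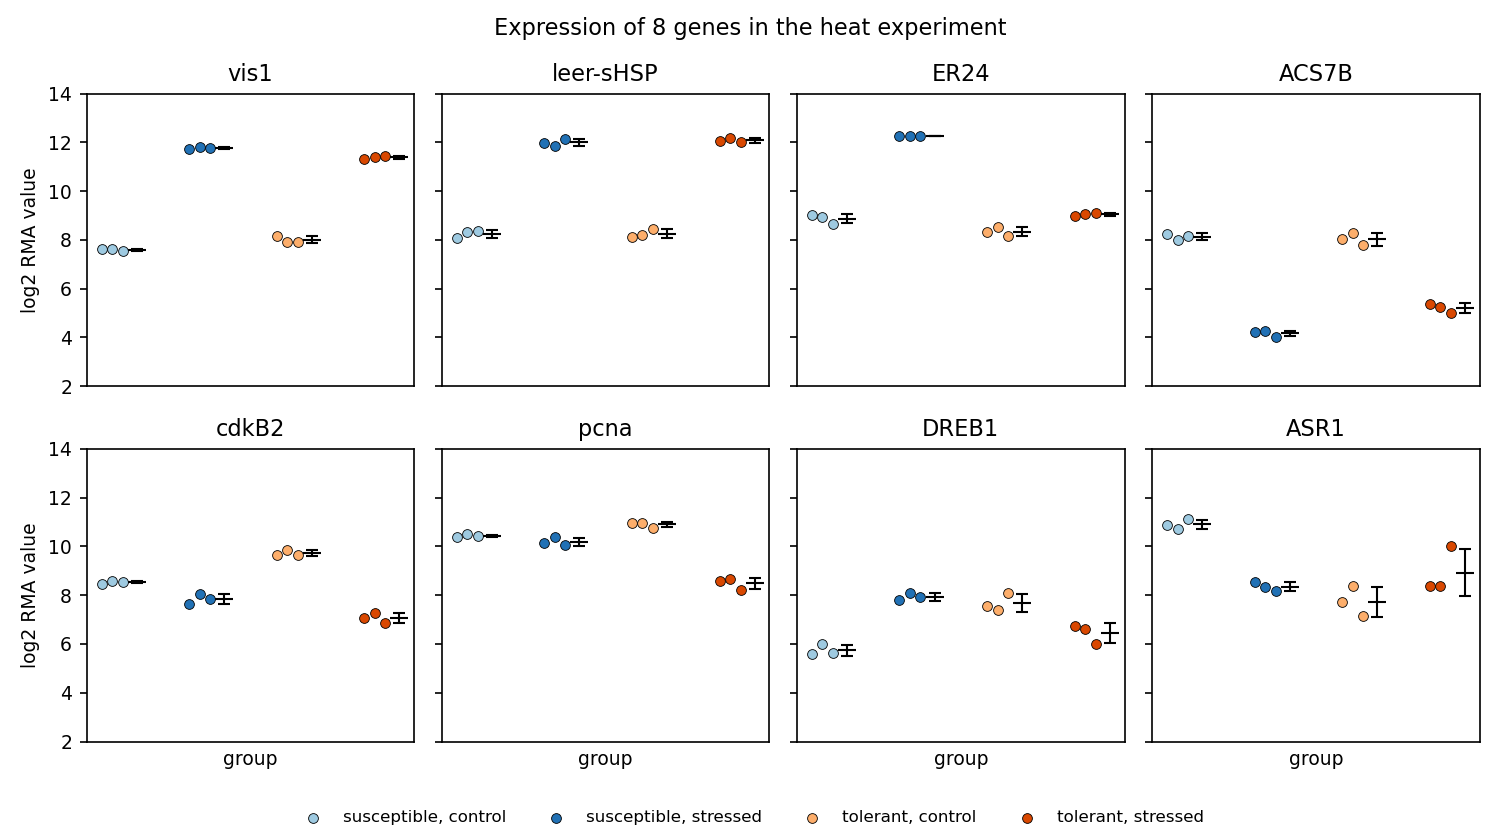
Log2 expression of 8 genes in the heat experiment, with 3 arrays per group as points and the mean with its SD as bars. vis1 and leer-sHSP rose by 3.39 to 4.17 in both genotypes, ER24 rose by 3.40 in susceptible and 0.70 in tolerant plants, and DREB1 rose by 2.20 in susceptible and changed by -1.24 in tolerant plants.

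The difference was called for 2786 probe sets, 1566 with a higher and 1220 with a lower response in tolerant plants, or 1205 and 1778 after centring of arrays and 1341 and 1428 after repeated quantile normalization. The count was 1855 without susceptible control replicate 1, 1794 without susceptible stressed replicate 3 and 4512 without tolerant control replicate 2, and array weights gave 6309. Both genotypes shared 788 increases, against 363.2 for independent lists, and 447 decreases against 235.3. A further 79 probe sets rose in susceptible and fell in tolerant plants, against 312.2 for independent lists, and 122 went the other way against 273.7.

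In control plants of the heat experiment, 8 of the 9 histone and cell cycle genes were higher in tolerant leaves, also over the list alone (adjusted p = 0.000935, and adjusted p = 0.713 with an estimated correlation), such as CycB2 (at least 1.18) and CycD3;3 (1.22). The extensin-like LOC543740 was higher by at least 3.04 (adjusted p = 4.65e-06), TPP3 by 3.44 ± 0.13 and TGAS118 by 2.45 ± 0.16. Lehsp90-2 was at -2.07 or lower. Lower genes also included GRAS1 (-2.46 or lower), the arginine decarboxylase adc1 (-3.18 or lower), ARF2 (-3.32 ± 0.44) and ASR1 (-3.17 ± 0.42), and TPI (2.49 ± 0.31) was higher. Of the flower and pollen markers 6 were higher and 1 lower of 7, also over the list alone (adjusted p = 0.123), and 4 of the 6 lay within the reporter range. Reporter probe sets were higher as well, by a median of 0.87 with 48 of 63 called.

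In stressed plants, large chaperones were lower in tolerant leaves in 6 of 9 cases and higher in none, also over the list alone (adjusted p = 0.00971, and adjusted p = 0.276 with an estimated correlation), with HSP90 at -1.53 or lower, Lehsp90-2 at -1.87 and BiP/grp78 at -1.81. Cell wall genes were higher in 16 and lower in 2 of 28 cases (18 and 3 over the list alone; adjusted p = 0.00971, and adjusted p = 0.276 with an estimated correlation), led by LOC544158 (2.62). The inhibitor mcpi was higher by 3.56 ± 0.16 (adjusted p = 1.04e-07), the growth repressor relative LeGAI by 3.48 ± 0.27, NP24-I by 2.90 ± 0.26 and the proteinase inhibitor LOC543954 by 2.79 ± 0.12. ER24 was lower (-3.22 ± 0.12), as were Eli3 (-2.47 ± 0.16), PPCK2 (-2.22 ± 0.16) and SAR2 (-1.97 ± 0.17).

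The genotypes differed at 5872 probe sets in control plants, 3191 higher and 2681 lower in tolerant leaves, or 4636 and 2082 after centring, which set the median of all probe sets at 0.29 rather than 0.08. Without the dimmest 25 percent the split turned, with 2024 higher and 2547 lower. In stressed plants they differed at 3157, 1809 higher and 1348 lower, with no reporter probe set called, and array weights gave 6728. Of all probe sets tested, called or not, 66.25% in control and 52.34% in stressed plants had replicates that did not overlap. With the gapdh covariate, chosen after seeing the data, 194 calls were left in control plants. GRAS1 (-0.92), adc1 (-1.24), ARF2 (-0.20), ASR1 (-0.47), TPI (0.58), CycB2 (1.81) and CycD3;3 (0.88) were no longer called. The gapdh signal itself was 1.60 in susceptible and 4.78 in tolerant control arrays, so lost calls do not tell RNA integrity apart from genotype.

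Drought and heat responses, each averaged over both genotypes of its experiment, correlated across 10101 probe sets at r = 0.228 (Spearman rho = 0.216). Probe sets are not independent replicates. Both experiments shared 1344 increases, against 830.9 for independent lists, and 735 decreases against 572.2. Between drought-susceptible and heat-susceptible plants these were 509 increases against 282.9 and 404 decreases against 182.3. The labels do not say that these plants were of a single genotype, nor do they for the tolerant plants. Between drought-tolerant and heat-tolerant plants the shared increases were 1258 against 820.2 and the shared decreases 622 against 596.1, and for these decreases no excess was found (Fisher p = 0.167). Among named genes, most cell cycle genes fell under both stresses, and sus3 rose under both, by 2.12 and 3.05 under drought and by 2.07 and 1.61 under heat in susceptible and tolerant plants. The small heat shock proteins rose under heat in both genotypes, and under drought HSP21, vis1 (3.01) and leer-sHSP (2.51) rose in susceptible plants, while HSP17.4 changed by -2.74 (adjusted p = 1.81e-05) and LEMTSHP by -0.81 (adjusted p = 0.0875). That list had 3 higher and 1 lower of 5 genes (adjusted p = 0.625), or 3 and 2 after repeated quantile normalization. The wall transferase ext, which fell in both genotypes under drought, changed by -0.04 (adjusted p = 0.878) and 0.11 (adjusted p = 0.4) under heat.

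The fold changes of the authors' deposited tables were set against the differences of group means computed here. For drought they correlated at 0.9949 in the susceptible and 0.9878 in the tolerant genotype over 2216 probe sets, and 96.84% and 96.8% had the same sign. For heat the authors' deposited table gave 0.9963 and 0.996 over 1210 probe sets, with 96.69% and 98.6% of the same sign. The largest difference for a probe set was 2.13 in susceptible and 4.12 in tolerant drought plants, and 0.675 and 1.07 for heat. Of the probe sets in the authors' deposited tables, 1998 (90.16%) for drought and 1157 (95.62%) for heat were called here for the difference of responses. The tables had been selected for that difference on these same samples, so neither the shares nor the correlations are independent support.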

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

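The tests with RNA integrity covariates, with the reporter probe sets, without tolerant control replicate 3 and of a single wrong label among drought arrays were chosen after the results were seen. The difference of drought responses, called for 3753 probe sets, and that of heat responses, called for 2786, were tested directly and are listed since both genotypes responded differently. In the drought experiment 560 probe sets, PR1b1 and P4 among them, were called in both genotypes with opposite directions and for the difference itself. In the heat experiment there were 201 such probe sets, DREB1, PPCK1 and PPCK2 among them, whose changes in tolerant plants were not called with the gapdh covariate (-0.33, -0.77 and -0.39). For drought, 1 of 100 regroupings of the genotype labels within conditions, the real one, gave as many calls as the 3753, with 3383 as the highest other count. For heat, 3 of 100 regroupings did, with 3724 called when 2 labels were exchanged in 1 condition alone and 3297 when 1 and 3 were, and the cause was not tested. Exchanged labels put differences between genotypes into the residual spread, and 83 of the 99 other regroupings in each experiment called nothing, so these counts decide little about a random grouping of the arrays.

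The bioB spike-in stood 5.12 higher on the tolerant than on the susceptible drought arrays, where the genotypes differed at 5912 probe sets in control and 6852 in stressed plants. A repeated quantile normalization kept 0.8219 of the calls in control plants with their sign. This argues against remaining differences in the range of values between arrays as the whole cause of those calls. It started from the deposited values and keeps the order of probe sets on each array, so it cannot decide about the authors' normalization itself. Reporter probe sets, which match no tomato gene, were called at a share of at least 0.4921 in both conditions, so a difference in array handling or in the amount of labelled RNA may account for part of the calls. The biological difference that the design names, the genotype, remains open, since all tolerant drought arrays share this signal, their mean 3' minus 5' signal was higher too (2.89 and 1.64 against 1.25 and 0.75), and the effects cannot be separated.

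PR1b1, P4 and many other genes responded in opposite directions to drought in the 2 genotypes. The tolerant arrays had a narrower range of values, with an SD over probe sets of 2.39 and 2.30 against 2.65 and 2.69. Quantile normalization, which gives all arrays a single range, kept 0.8737 of the 3753 calls with their sign, which argues against that range as the whole cause, and each array correlated better with its own group than with any other, by at least 0.0719, which argues against a label exchanged among these 4 groups for a single array. Exchanged control and stressed labels in 1 genotype would reverse its other changes too, yet both responses correlated at 0.487, with TAS14 higher under drought in both, which speaks against such an exchange only if the genotypes share most of their response. A genotype difference in the drought response, unequal handling of the arrays or another defence status of the plants could be followed up, and no test here separated them.

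The heat response of the tolerant genotype coincided with a gapdh 3' minus 5' signal 2.13 higher in control than in stressed arrays and with 45 reporter probe sets called of 63. Without tolerant control replicate 3, the array with the highest gapdh and reporter values, 0.89 of the 5564 calls kept their sign and call, which argues against that array as the whole cause. A covariate of 3 control transcripts kept 0.9107 of the calls, but it barely differed between control and stressed arrays (4.45 and 4.13) and decides little, since actin was similar (4.48 and 4.01) and ef1a lower in control arrays (4.09 and 5.74). With the gapdh covariate 0.3001 of the calls were kept, and 43 of 98 shuffles of that covariate within groups kept as few, so what the gapdh signal alone measures cannot be told apart from the response to heat, and the 3 transcripts did not agree on a loss of RNA integrity. The share of reporter probe sets called, 0.7143, fits a higher background on tolerant control arrays, which may account for part of the decreases. Yet the 5 named small heat shock proteins rose in both genotypes.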

How the results depend on the processing

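The covariates and the removal of replicate 3 of both tolerant heat groups were chosen after the results were seen. Direction was followed only for genes in comparisons where the main fit called them. Among these, no gene discussed turned its direction under any alternative, but calls ended for some. With all 24 arrays in a single model these were ER24 in tolerant plants (0.70), LEMTSHP (-1.01) and vis1 (-0.78) for the difference of responses and cdkB2 in susceptible plants (-0.68), all under heat. With the gapdh covariate ER24 stood at 0.37 in tolerant plants, with the RNA integrity covariate Lehsp90-2 stood at -1.48 between stressed heat plants, and after quantile normalization LOC544058, within the reporter range, stood at 0.71 in tolerant drought plants. With a log2 difference of at least 1, counts were 2445, 2878 and 3667 for drought in susceptible plants, tolerant plants and between control plants. For heat they were 752, 2212, 1508, 2155 and 857 for susceptible plants, tolerant plants, the difference of responses, control plants and stressed plants. Calls shared by both genotypes in the same direction, counted over the drought and heat experiments together, went from 3493 to 1335. Array weights gave 7435 for drought in susceptible plants, and for heat 5472 in susceptible plants, 6309 for the difference of responses and 6728 between stressed plants. Only the 6 arrays compared gave 7502 and 3109 for drought and 4431 and 3174 for heat in susceptible and tolerant plants, a fit with fewer arrays in which the spread of the other genotype has no part. The RNA integrity covariate gave 3317 between control plants of the drought experiment and 2744 and 1445 between control and stressed plants of the heat experiment. The gapdh covariate gave 3424 and 2445 for heat in susceptible and tolerant plants and 194 between control plants. Without replicate 3 of both tolerant heat groups, 3891 were called in susceptible plants and 5516 between stressed plants. Removal of single arrays gave between 1794 and 4512 for the difference of heat responses, with 1855 without susceptible control replicate 1, 1794 without susceptible stressed replicate 3 and 4512 without tolerant control replicate 2, and no other count moved by over 1.5 times. Except where the construction of the alternative shows it, the cause was not tested.

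Of 160 tests of lists, 20 passed, 3 with an estimated correlation, 123 with fry, which does not compare a list with other genes, and 46 with unnamed probe sets in the background. The 3 were cell wall and PR genes for drought and small heat shock proteins for heat, all in susceptible plants. The drought and heat responses correlated at 0.298 without the dimmest probe sets. Between drought-tolerant and heat-tolerant plants, which the labels do not call a single genotype, they correlated at 0.134. The replicate numbers did not pair the arrays throughout, since deviations of same-numbered arrays correlated between -0.127 and 0.115 for drought and between -0.339 and 0.36 for heat. Between susceptible control and stressed heat arrays, same-numbered ones correlated between 0.082 and 0.211 and others between -0.231 and 0.061, so a pairing there stays open. Between tolerant control and stressed heat arrays, same-numbered ones correlated between -0.266 and -0.074. With replicate numbers as a block, counts were 4165, 4947, 3572, 5782 and 6765 for drought and 2075, 5451, 2639, 5810 and 2984 for heat, in the order of the report. Of 18 comparisons each, an array correlated best with its own number in 4 for drought and 8 for heat. Signal near background limits what the tolerant heat controls show, where removal of the dimmest 25 percent of probe sets left 2845 higher and 1447 lower for heat in tolerant plants and 2024 higher and 2547 lower between control plants.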

Other observations

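Tests reported here on further lists were planned, and the choice of which to describe was made after the results were seen. Named genes had been selected on these samples for a difference of responses. That difference was called here for 90.16% of the probe sets in the authors' drought table and 95.62% in their heat table. Counts of differing responses therefore say little about a list. Some antioxidant genes responded differently to drought in the 2 genotypes, but no test of the list passed. Of 9 named genes, 6 were higher and 2 lower in susceptible plants (adjusted p = 0.549) and 1 was higher and 5 lower in tolerant plants (adjusted p = 0.696), and the response was lower in tolerant plants for 7 and higher for 2 (adjusted p = 0.224 for the list). The iron superoxide dismutase FESOD changed by 2.05 in susceptible and by -0.89 in tolerant plants, and its responses differed by -2.94. The ascorbate peroxidase APX1, which removes hydrogen peroxide, changed by 0.35 and -1.39. The dehydroascorbate reductase DHAR1 rose in both, by 1.38 and 2.30, and the transferase BI-GST/GPX changed by -2.90 in susceptible and by 0.23 (adjusted p = 0.178) in tolerant plants. In stressed plants, amino acid and nitrogen genes were lower in tolerant leaves for 6 and higher for 1 of 8 (adjusted p = 0.0684), with the glutamate dehydrogenase legdh1 at -2.83 and the asparagine synthetase AS1 at -2.72. The sugar carriers HT2 and ht1 parted in susceptible plants under drought, with HT2 at 3.21 in susceptible and -1.23 in tolerant plants, the latter not called from the 6 tolerant arrays alone, and ht1 at -3.62 and -3.76.

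Under heat, single ethylene and wound genes rose in the tolerant genotype, but no test of these lists passed. Of 23 ethylene genes, 16 were higher and 4 lower in tolerant plants (16 and 5 adjusted over the list alone; adjusted p = 0.188) and 8 were higher and 5 lower in susceptible plants (8 and 6 over the list alone; adjusted p = 0.497). The response was higher in tolerant plants for 13 and lower for 5 (adjusted p = 0.383). The oxidase ACO6, of ethylene synthesis, rose by 2.30 in tolerant plants, and the receptor Never-ripe rose in both genotypes, by 1.54 and 1.68. Of 15 jasmonate and wound genes, 9 were higher and none lower in tolerant plants (adjusted p = 0.261), and repeated quantile normalization or centring made this 9 and 2. The response was higher in tolerant plants for 8 and lower for 1 of them (9 and 1 over the list alone; adjusted p = 0.347). The proteinase inhibitor ER1 changed by -0.56 or lower in susceptible and by at least 0.28 in tolerant plants, and the lipoxygenase loxD by -2.33 in susceptible and by -0.43 (adjusted p = 0.0648) in tolerant plants, where several alternatives called it lower, such as quantile normalization (-0.67). NCED1 changed by -0.96 in susceptible and by 1.05 in tolerant plants, and its responses differed by 2.01. With the gapdh covariate its change in tolerant plants was 0.53 and not called, which does not tell RNA integrity apart from heat.

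Each response within a genotype and each difference between genotypes compared 3 arrays with 3, where only 10 splits exist and a share under 0.05 cannot be reached. In all 8 of these comparisons 1 of 10 splits, the real one, gave as many calls. For drought the real and highest other counts were 4324 and 0 in susceptible plants, 5110 and 57 in tolerant plants, 5912 and 0 between control plants, and 6852 and 0 between stressed plants. For heat they were 2150 and 0, 5564 and 1, 5872 and 0, and 3157 and 0 in the same order.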
